A study of Aphis gossypii with 6 samples.

How the data were processed

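RNA from pooled whole bodies of Aphis gossypii was sequenced in 6 libraries, 3 from a strain resistant to beta-cypermethrin and 3 from a susceptible strain. Per the labels' protocols, RNA was extracted with a phenol-based reagent and made into libraries with an NEBNext Ultra RNA kit; a strand setting is not given in the sources used here, so a gene and an overlapping or antisense gene cannot be told apart. The submitters' processing notes name fastp 0.22.0 and HISAT2. The counter, the annotation and the genome build are not given in the sources used here.

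The data are 1 table of 14013 genes. Per the file headers, the authors gave whole-number read counts for each library, not normalized, and FPKM values for the same libraries. They also gave the adjusted p-value and log2 fold change of a DESeq2 comparison of the strains, per the file headers, and these deposited values are printed only where the authors' deposited table is named. The deposited FPKM values were not tested; they served only to derive each gene's effective length from its counts. Gene names and product descriptions are those in the table. Of 12815 identifiers of the RefSeq LOC kind, 10738 matched the reference table of assembly ASM2018417v2, and 1198 further loci carry names given by the authors. As the build of the table is not stated, no coordinates were used.

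Groups were taken from the sample titles. Raw counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood F test on strain alone, Benjamini-Hochberg adjusted p under 0.05). The filter left 11149 genes, and 1085 of the 14013 had no count. Log2 fold changes are resistant over susceptible; SE is the size of the log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes, except that genes counted in 1 strain were chosen on CPM from plain library totals. Where a gene had 0 counts in all libraries of a strain, the fold is a lower bound from a floor of 3 counts over the group, which covers counting error only. The libraries held 31290134 to 46681719 counts. The script was tested on simulated counts for the resistant against susceptible comparison (11149 genes, 200 changed): it recovered 23.5% of 68 genes changed by 0.5 on the log2 scale, 74.2% of 66 changed by 1 and 95.5% of 66 changed by 2, with 6 unchanged genes among 134 calls.

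Before the data were examined, 29 gene lists were fixed as text patterns on the product descriptions, covering detoxification, insecticide targets, cuticle, digestion, metabolism, symbiosis, stress and tissue or stage markers. They were tested with limma 3.58.1 camera (two-sided, preset inter-gene correlation of 0.01, log2 CPM with a prior count of 2, lists of at least 3 tested genes), with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Camera compares a list with the other genes, whereas fry tests a list against no change. A pattern can match genes of another role, which are named where they moved. KEGG and Gene Ontology terms of 10 to 500 tested genes were tested with a one-sided Fisher's exact test against the tested genes with a term of that kind (3802 and 7894 genes), adjusted over all terms and both directions.

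Genes were named by a rule fixed at the same time. It takes every tested sodium channel gene. Then, among genes with an adjusted p under 0.05, at least a 2-fold change, at least 5 CPM in the higher strain and no overlap between the strains' libraries, it takes the greatest changes: up to 5 higher and 3 lower P450s, up to 2 per direction of esterases, glutathione S-transferases, UDP-glycosyltransferases, ABC transporters and cuticle proteins, 1 per direction of each other list with at least 3 called members or a list call, and 5 per direction among all annotated genes with at least 20 CPM. Members that make up a small count, the highest glutathione S-transferase, the second peroxiredoxin-6-like gene and list members with another role were named outside the rule after their values were seen.

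Alternatives were DESeq2's size factors within edgeR, library totals alone, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, CPM above 1 in at least 3 libraries, the replicate number as a block, leaving out each library, a test against a 2-fold threshold, and other list and term settings. All 6 libraries were kept as separate samples, as the labels list them. Libraries of a strain differed by more than counting noise (chi-square per degree of freedom between 7.23 and 134), as repeat preparations of 1 pool also would. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.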

Results

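Pooled whole bodies of the cotton aphid, Aphis gossypii, a sap-feeding crop pest, were sequenced as RNA from a strain resistant to the pyrethroid insecticide beta-cypermethrin and from a susceptible strain, with 3 libraries per strain. The comparison asks which genes differ in transcript level between the strains in the absence of the insecticide. The study's title names cytochrome P450s, which oxidise many insecticides, and the voltage-gated sodium channel, the protein that pyrethroids bind. Total counts were 31290134, 46681719 and 36429535 in resistant replicates 1 to 3 and 36110420, 32945033 and 31653431 in susceptible replicates 1 to 3. Between 11702 and 12072 of the 14013 listed genes had a count in each library. The labels do not say that the libraries of a strain came from separate cultures, so p-values measure the spread between these samples, which may be technical. As each condition is a single strain, a difference cannot be tied to resistance rather than to other differences between the strains.

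The first principal component of log2 CPM (counts scaled to a common library total) held 70.4% of the variance and parted the strains. The second held 16.4% and set resistant replicate 1 apart from the other resistant libraries. Within the resistant strain, 624 genes differed over 2-fold between replicates 1 and 2 and 875 between replicates 1 and 3, against 205 between replicates 2 and 3. The 3 susceptible pairs had between 218 and 247 such genes.

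**Figure D1:**
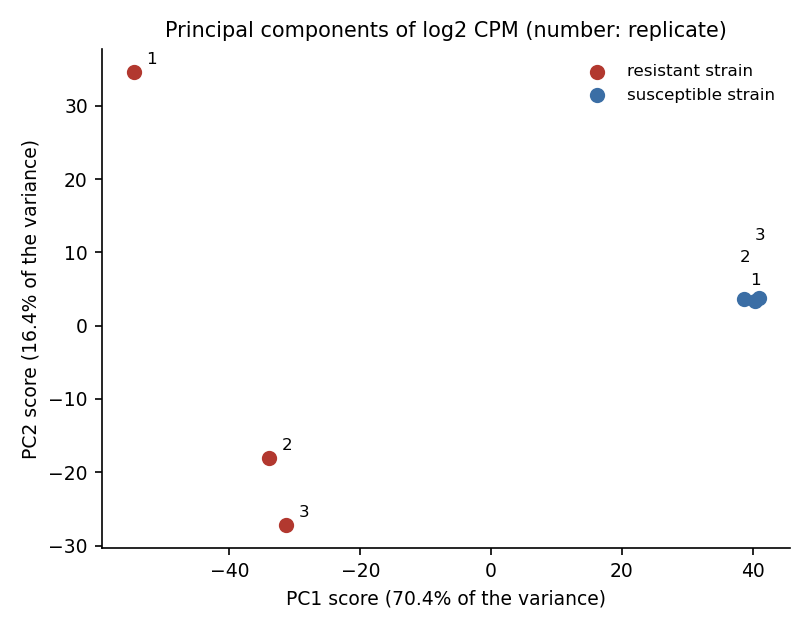
Scores of the 6 libraries on the first (x) and second (y) principal components of log2 CPM, in score units, 1 point per library with its replicate number. The strains part along the first component (70.4% of the variance), and resistant replicate 1 lies apart from resistant replicates 2 and 3 along the second (16.4%).

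In the resistant strain 2383 of 11149 tested genes were higher and 1611 were lower than in the susceptible strain (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among these, 926 were at least 2-fold higher and 219 at least 2-fold lower. The 3 libraries of each strain did not overlap in 6028 genes, 54.1% of those tested, where chance gives 10%. With libraries scaled by their totals alone the median of all genes moved by -0.15 on the log2 scale, and the calls became 1759 higher and 2322 lower, 43.1% higher in place of 59.7%. The 2-fold calls became 722 higher and 340 lower, 68.0% higher in place of 80.9%. The count of lower genes rose to 2826 without resistant replicate 1 and was 812, 788 and 789 without susceptible replicates 1, 2 and 3.

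Of 45 tested cytochrome P450 genes, 22 rose and 4 fell in the resistant strain, the same numbers when adjusted over the list alone. At least 2-fold rises were seen in 16, and 0 fell as much. The gene with the greatest increase was LOC114132928, a P450 6a13, which rose from 12.5 ± 0.66 to 132 ± 13.4 CPM (mean ± SD, n = 3 per strain), a log2 fold change of 3.41 ± 0.11 (SE, adjusted p = 2.69e-06). The 6g1-like LOC114123187 rose by 3.30 ± 0.16 on the log2 scale and reached 172 CPM, and the 6a20 gene LOC114123397 rose by 3.14 ± 0.21. The 4C1-like LOC114125146 rose by 2.94 ± 0.12. The 6k1-like LOC114123193 was the most abundant of these, with 436 ± 102 CPM in the resistant and 67.9 ± 4.8 in the susceptible strain. The 4 genes that fell were LOC114125149 (-0.97 ± 0.13), LOC114121977 (-0.62 ± 0.09) and the 49a1 genes LOC114122086 (-0.57 ± 0.13) and LOC114125936 (-0.42 ± 0.11). In the CYP6 family, linked to metabolism of plant compounds and insecticides in insects, 13 of 18 genes rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 fold change of 1.09. In the CYP4 family 7 of 14 rose and 1 fell, likewise adjusted over the list alone. The camera adjusted p was 3.64e-05 for all P450s, 4.51e-07 for CYP6 and 0.0322 for CYP4, and the adjusted p was 0.0613, 0.0595 and 0.203 in that order with an estimated correlation. Without resistant replicate 1, 3 CYP4 genes fell. The CYP4 adjusted p was 0.0682 without resistant replicate 1, 0.0517 without resistant replicate 3, 0.0767 with no low-count filter and 0.0875 with Swiss-Prot members alone. It was 0.0555 with the replicate number as a block.

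**Figure D2:**
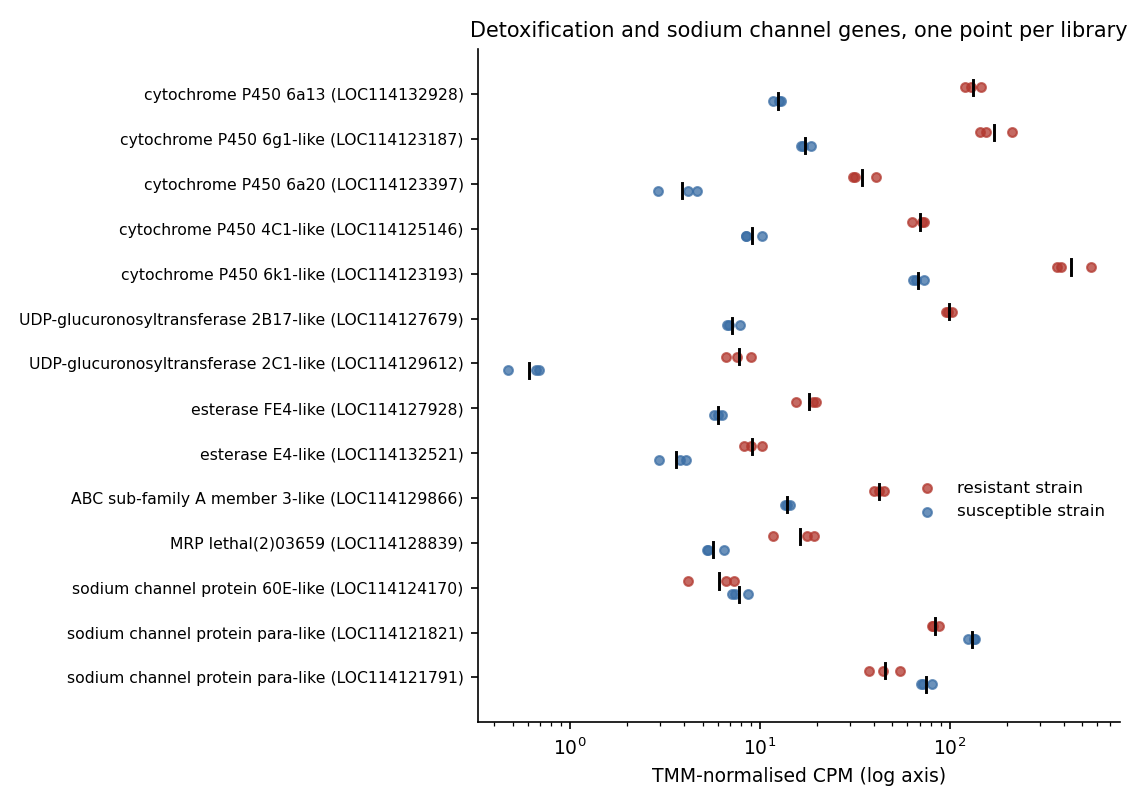
CPM after TMM normalisation (log x axis) of the named P450, UDP-glycosyltransferase, esterase, ABC transporter (ABC; MRP, multidrug resistance-associated protein) and sodium channel genes (y axis), 1 point per library and a black tick at each strain's mean, n = 3. All P450s shown lie higher in every resistant library, but the rule named only P450s without overlap between the strains' libraries. The para-like sodium channel genes LOC114121821 and LOC114121791, taken whatever their change, lie lower.

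UDP-glycosyltransferases, which attach sugars to lipophilic compounds, had the highest median log2 fold change of the 29 lists, 1.29. Of 45 tested, 37 rose and 2 fell, also when adjusted over the list alone, and 29 rose at least 2-fold (camera adjusted p = 2.98e-13; adjusted p = 0.103 with an estimated correlation). LOC114127679, a 2B17-like gene, rose from 7.17 ± 0.62 to 99.5 ± 3.8 CPM, by 3.80 ± 0.11 on the log2 scale (adjusted p = 1.9e-06). LOC114129612, a 2C1-like gene, rose by 3.67 ± 0.25 from 0.608 CPM. The 2 that fell were LOC114122387 (-2.17 ± 0.39) and LOC114122629 (-0.58 ± 0.15). Of 10 esterases, hydrolases that include the E4 and FE4 type linked to insecticide resistance in aphids, 6 rose and 1, LOC114131146 (-0.45 ± 0.11), fell. Adjusted over the list alone, 8 rose and 1 fell (camera adjusted p = 0.00108; adjusted p = 0.103 with an estimated correlation). The FE4-like LOC114127928 rose by 1.58 ± 0.15 and the E4-like LOC114132521 by 1.34 ± 0.19 on the log2 scale.

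Of 8 glutathione S-transferases 5 rose and 0 fell, also when adjusted over the list alone, but none reached 2-fold. The highest was LOC114127459, at 0.98 ± 0.15. The camera adjusted p was 0.0139, and the adjusted p was 0.194 with an estimated correlation and 0.0706 with Swiss-Prot members alone. Without susceptible replicate 1 or 3 the count that rose was 3. Of 68 ABC transporters, membrane pumps, 26 rose and 2 fell, 8 of them rising at least 2-fold (26 and 3 adjusted over the list alone; camera adjusted p = 0.00241; adjusted p = 0.203 with an estimated correlation). LOC114129866, an A-family member, rose from 14.0 ± 0.42 to 42.5 ± 2.7 CPM, and LOC114128839, a multidrug resistance-associated protein, from 5.70 ± 0.69 to 16.3 ± 4.0 CPM. With library totals alone 16 ABC genes rose and 4 fell. Without resistant replicates 1 and 3 the ABC genes that fell were 9 and 4. The median deviation of resistant replicate 1 from the other resistant libraries was -0.04 on the log2 scale for P450s, -0.09 for ABC transporters and 0.22 for UDP-glycosyltransferases. Single genes deviated more. Each CYP6 gene named above was highest in resistant replicate 1, such as LOC114123193, with 553 CPM against 385 and 370 in resistant replicates 2 and 3. The 4C1-like LOC114125146 was lowest there, with 63.6 CPM against 73.7 and 71.7. Many members of these families are close copies, and the way reads shared between copies were counted is not given in the sources used here, so values of single members are uncertain.

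Of the 3 tested sodium channel genes, the 2 para-like ones had lower transcripts in the resistant strain. Para is the channel that pyrethroids bind. The para-like sodium channel gene LOC114121821 fell from 132 ± 5.9 to 83.6 ± 4.2 CPM, by 0.66 ± 0.08 on the log2 scale (adjusted p = 0.000608). The other para-like gene, LOC114121791, fell from 74.9 ± 5.5 to 45.6 ± 8.5 CPM (-0.72 ± 0.14, adjusted p = 0.00539). The 60E-like channel LOC114124170 was at 6.08 ± 1.7 CPM in the resistant and 7.76 ± 0.83 in the susceptible strain, a difference within the spread of the libraries (adjusted p = 0.268). The same 2 genes passed when adjusted over the list alone. The list of 3 had a camera adjusted p of 0.0430, with an adjusted p = 0.203 with an estimated correlation, 0.0682 without resistant replicate 1, 0.0559 without susceptible replicate 3 and 0.0668 with library totals alone. Of 23 genes for receptors and enzymes that other insecticides act on, 11 fell and 4 rose, also when adjusted over the list alone, with a median log2 fold change of -0.41 (camera adjusted p = 0.0139; adjusted p = 0.307 with an estimated correlation). The fallen ones included the alpha-7-like acetylcholine receptor subunit LOC114132690 (-1.01 ± 0.22). Acetylcholine receptor subunits LOC114125369 (1.33 ± 0.21), LOC114124551 (1.23 ± 0.21) and LOC114123921 (1.17 ± 0.15) rose. The remaining riser, LOC114133115, is a GABA receptor-associated protein, which acts in autophagy and receptor trafficking and is no receptor. Sequence variants of the channel were not analysed here.

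Of 53 cuticle protein genes, which form the insect's outer shell, 32 rose and 3 fell (36 and 4 adjusted over the list alone), with 22 rising at least 2-fold and a median log2 fold change of 0.80 (camera adjusted p = 1.14e-05; adjusted p = 0.567 with an estimated correlation). LOC114126129 rose from 4.12 ± 0.91 to 33.8 ± 10.5 CPM and LOC114124292 from 31.8 ± 4.6 to 197 ± 97 CPM, while LOC114126671 fell from 758 ± 42 to 292 ± 123 CPM. Cuticle genes had the largest median deviation of the 29 lists in resistant replicate 1, 0.74 log2 units above the other resistant libraries, and without that library the list median was 0.51 and 5 of its genes fell. The number that fell was 1 without resistant replicate 2 and without each susceptible replicate in turn, 1, 2 and 3, and 5 with library totals alone. In chitin metabolism 8 of 13 genes rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.00108; adjusted p = 0.274 with an estimated correlation). Endochitinase LOC114129495 rose from 718 ± 30 to 1709 ± 377 CPM. Chitin genes were 0.27 log2 units higher in resistant replicate 1 than in the other resistant libraries.

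Aphids feed on phloem sap rich in sucrose. Of 96 tested sugar transporters and enzymes of sugar metabolism 63 rose and 3 fell, 35 rising at least 2-fold (71 and 5 adjusted over the list alone; camera adjusted p = 5.54e-12; adjusted p = 0.193 with an estimated correlation). Maltase LOC114128186 rose from 23.3 ± 2.3 to 220 ± 21 CPM, by 3.24 ± 0.12 on the log2 scale. Resistant replicate 1 lay 0.29 log2 units above the other resistant libraries in this list, and without it 8 genes fell, without resistant replicate 2 and without susceptible replicates 1, 2 and 3 only 1 fell each time, and with library totals alone 7 fell. Of 55 digestive peptidase genes 33 rose and 1 fell, and 24 rose at least 2-fold (33 and 3 adjusted over the list alone; camera adjusted p = 1.57e-06; adjusted p = 0.307 with an estimated correlation). Their median was 0.87, or 0.66 without resistant replicate 1, which lay 0.40 log2 units above the other resistant libraries in this list and without which 5 genes fell. With library totals alone 4 fell. The list's greatest increase was in Aphis_gossypii_newGene_3096, an antichymotrypsin that inhibits peptidases in place of digesting protein, with 20 counts in all susceptible and 899 in all resistant libraries. In fatty acid and hydrocarbon synthesis 35 of 60 genes rose and 3 fell (36 and 5 adjusted over the list alone), with a camera adjusted p of 1.14e-05 and an adjusted p = 0.0595 with an estimated correlation. With library totals alone 5 of them fell. The desaturase LOC114119128 rose from 72.6 ± 4.9 to 322 ± 96 CPM, and the fatty acid synthase LOC114129891 fell from 5.21 ± 0.26 to 0.412 ± 0.041 CPM.

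Among 49 antioxidant genes 28 rose and 2 fell (30 and 2 adjusted over the list alone), with a median log2 fold change of 0.49 (camera adjusted p = 8.06e-07; adjusted p = 0.0842 with an estimated correlation). Chorion peroxidase LOC114131762, named for a role in the eggshell and matched to this list by its text, rose from 1.95 ± 0.20 to 11.4 ± 1.4 CPM. The peroxiredoxin-6-like gene LOC114126282 had 0 counts in all 3 resistant libraries and 16.4 ± 0.58 CPM in the susceptible strain, at least 598-fold lower against a floor of 3 counts over the resistant group. As sequence was not analysed here, a lower transcript level cannot be told apart from a copy that is missing or does not match the reference. A second gene with that name, LOC114132436, rose by 0.49 ± 0.11 on the log2 scale, to 78.5 CPM.

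Aphids house bacterial symbionts in bacteriocytes that exchange amino acids with them. Of 8 genes matched to this role, 7 rose and 0 fell (7 and 1 adjusted over the list alone), with a median log2 fold change of 1.15 (camera adjusted p = 0.00192; adjusted p = 0.203 with an estimated correlation). Cystathionine gamma-lyase LOC114125121, an enzyme of sulfur amino acid metabolism, rose by 2.56 ± 0.20 on the log2 scale, to 235 ± 75 CPM. The list median was 0.48 higher in resistant replicate 1 than in the other resistant libraries and was 0.99 without it. Its member LOC114123976 is a folylpolyglutamate synthase, an enzyme of folate metabolism that only matched the text pattern. Of 9 carotenoid genes, which aphids carry for pigment synthesis, 6 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.00414; adjusted p = 0.203 with an estimated correlation). Without susceptible replicate 3 the count that rose was 3, and resistant replicate 1 lay 0.25 log2 units above the other resistant libraries. The lycopene cyclase/phytoene synthase LOC114125977 rose from 8.78 ± 0.99 to 40.4 ± 2.7 CPM.

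Of 61 mitochondrial respiratory chain genes 28 rose and 1 fell (30 and 1 adjusted over the list alone; median 0.33; camera adjusted p = 1.47e-05; adjusted p = 0.452 with an estimated correlation). Resistant replicate 1 lay 0.24 log2 units above the other resistant libraries in this list, and the median was 0.24 without it. The number rising was 17, 17 and 12 without susceptible replicates 1, 2 and 3, and 17 with library totals alone. LOC114129850, a subunit of complex I, rose by 1.11 ± 0.23 on the log2 scale. Of 83 ribosomal protein genes 21 fell and 4 rose (17 and 4 adjusted over the list alone), with a median of -0.29 (camera adjusted p = 1.47e-05; adjusted p = 0.650 with an estimated correlation and 0.171 with fry). The count that fell rested on single libraries. It was 71 without resistant replicate 1, in which these genes lay 0.44 log2 units above the other resistant libraries, 9 and 11 without resistant replicates 2 and 3, and 7, 6 and 8 without susceptible replicates 1, 2 and 3. With library totals alone 61 fell. L39, LOC114127992, went the other way and rose from 67.9 ± 9.0 to 239 ± 68 CPM.

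**Figure D3:**
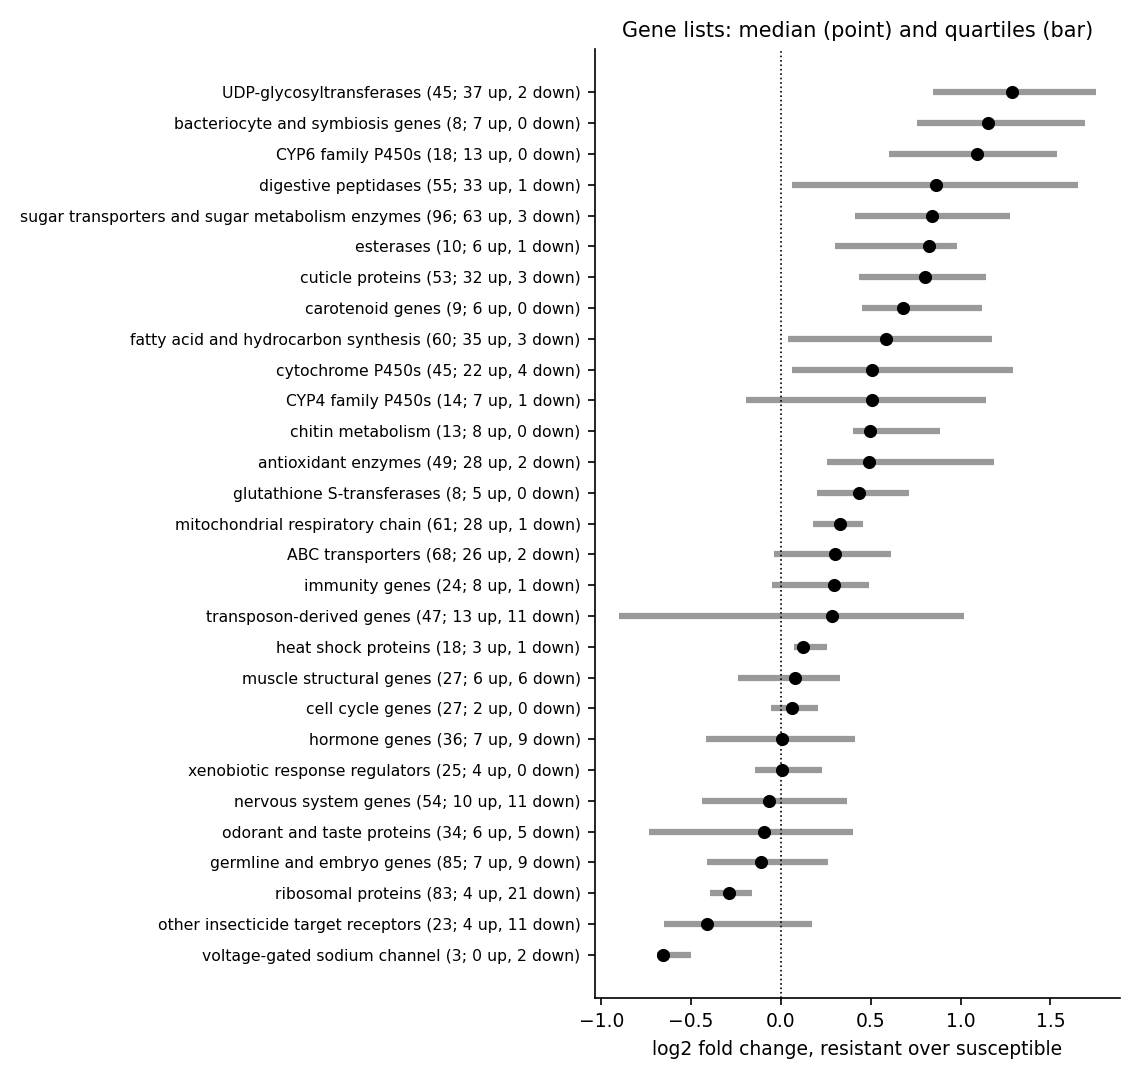
Median (point) and quartiles (bar) of the log2 fold changes, resistant over susceptible (x axis), for the 29 gene lists (y axis), with the number of genes tested and the numbers that passed the gene test higher and lower. UDP-glycosyltransferases have the highest median (1.29) and the 3 sodium channel genes the lowest (-0.66), and with libraries scaled by totals alone all values move down by about 0.15.

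Lists for tissues, stages and stress other than detoxification mostly did not pass the list test. In muscle structural genes 6 rose and 6 fell of 27 (camera adjusted p = 0.906), in nervous system genes 10 rose and 11 fell of 54 (0.372), in germline and embryo genes 7 rose and 9 fell of 85 (0.219), in cell cycle genes 2 rose and 0 fell of 27 (0.725), and in hormone genes 7 rose and 9 fell of 36 (0.527). In odorant and taste proteins 6 rose and 5 fell of 34 (0.503), in xenobiotic response regulators 4 rose and 0 fell of 25 (0.788), in heat shock proteins 3 rose and 1 fell of 18 (0.372), in transposon-derived genes 13 rose and 11 fell of 47 (0.420), and in immunity genes 8 rose and 1 fell of 24 (0.0568). The immunity list had an adjusted p of 0.0326, 0.0252 and 0.0395 without resistant replicate 2, resistant replicate 3 and susceptible replicate 3. It also passed with DESeq2 (0.0415), no low-count filter (0.0427), fry (0.0226) and Swiss-Prot members alone (0.00817), and the transposon-derived list passed with fry (0.00176). The fry test asks whether a list changed at all, not whether it changed more than the other genes. Adjusted over the list alone, the numbers higher and lower were 6 and 6 for muscle, 10 and 13 for nervous system, 6 and 9 for germline, 1 and 0 for cell cycle and 8 and 9 for hormone genes. They were 5 and 5 for odorant and taste, 4 and 0 for xenobiotic response, 3 and 1 for heat shock, 14 and 12 for transposon-derived and 8 and 1 for immunity genes. The nervous system list had a median of -0.06 and a mean of 0.02, and the hormone list a median of 0.01 and a mean of 0.06 with a camera direction of lower. Resistant replicate 1 lay 0.40 log2 units above the other resistant libraries in immunity genes, 0.36 above in heat shock proteins and 0.29 below in cell cycle genes.

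These counts depended on single libraries, and moves beyond 1.5-fold and beyond 1 gene were as follows. Without resistant replicate 1, 13 cell cycle genes rose, 12 germline genes rose and 25 fell, 5 heat shock proteins rose and 6 fell, 10 muscle genes rose, and 14 hormone, 5 immunity, 17 nervous system, 8 odorant and taste and 5 xenobiotic response genes fell. Without resistant replicate 2, 2 muscle genes rose, and 7 nervous system and 7 transposon-derived genes fell. Without susceptible replicate 1, 5 immunity, 2 muscle and 3 odorant and taste genes rose, and 3 germline, 5 nervous system and 5 transposon-derived genes fell. Without susceptible replicate 2, 2 muscle and 0 odorant and taste genes rose, and 3 muscle, 6 nervous system and 5 transposon-derived genes fell. Without susceptible replicate 3, 2 muscle and 0 odorant and taste genes rose, and 3 muscle, 4 germline, 6 nervous system and 6 transposon-derived genes fell. With library totals alone 3 muscle and 0 cell cycle genes rose and 19 germline and 2 xenobiotic response genes fell, and the medians of the cell cycle, heat shock, muscle, hormone and xenobiotic response lists turned from above to below 0.

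Single members of these lists still differed. Most were named by the rule, which takes only changes of at least 2-fold without overlap between the strains' libraries. Phenoloxidase LOC114129930, an enzyme of melanin formation and defence, rose from 10.4 ± 1.6 to 55.4 ± 9.5 CPM, and titin-like LOC114127264 from 24.7 ± 2.7 to 96.3 ± 38.9 CPM. Takeout-like LOC114123062 rose by 2.15 ± 0.29 on the log2 scale and the syntaxin LOC114132940 by 1.79 ± 0.25. LOC114127259, described as tetra-peptide repeat homeobox protein 1-like and matched to the germline list by its text, rose by 1.90 ± 0.22. Each of these genes was highest in resistant replicate 1. Titin-like LOC114127264 had 141 CPM there, against 80.0 and 68.3 in resistant replicates 2 and 3. The 4 members of the xenobiotic response list that rose included NADPH-cytochrome P450 reductase LOC114131750 (0.81 ± 0.09), which passes electrons to P450s, and the nuclear receptor LOC114126052 (0.47 ± 0.12). The others, LOC114119520 (1.27 ± 0.16) and LOC114122071 (0.93 ± 0.20), are membrane hormone receptors matched by their text. A role of theirs in this response was not tested. Odorant-binding protein LOC114122382 rose by 1.10 ± 0.25, with an adjusted p of 0.0508 and 0.0542 without susceptible replicates 2 and 3, and the sugar taste receptor LOC114121499 fell by 1.09 ± 0.19. Among transposon-derived genes Aphis_gossypii_newGene_1839 rose by 1.60 ± 0.28. The tigger element LOC114120105 fell (-1.10 ± 0.35, adjusted p = 0.0409), but its adjusted p was 0.0589 without resistant replicate 2 and 0.113, 0.130 and 0.0750 without susceptible replicates 1, 2 and 3.

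Among annotated genes with at least 20 CPM in the higher strain, the 5 with the greatest increase were the UDP-glycosyltransferase LOC114127679, the P450s LOC114132928 and LOC114123187, the maltase LOC114128186 and LOC114126754. The last, a subunit of the V-type proton pump that acidifies organelles and gut lumen, rose from 2.88 ± 0.25 to 29.6 ± 3.6 CPM. The 5 with the greatest decrease changed less. RFX2-like LOC114129314, a transcription factor of the family that directs cilium genes in animals, fell from 85.9 ± 0.70 to 28.5 ± 3.4 CPM (-1.59 ± 0.11, adjusted p = 3.66e-05). It was followed by the cuticle protein LOC114126671 (-1.38 ± 0.27), the signalling adaptor LOC114120558, TRAF6-like (-1.38 ± 0.11), LOC114120963, a part of the anaphase-promoting complex (-1.36 ± 0.15), and the mpv17-like LOC114122338 (-1.36 ± 0.15).

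Annotation terms were tested with a one-sided Fisher's exact test on genes changed at least 2-fold. Among genes that rose, 20 of 131 KEGG pathways and 171 of 2957 Gene Ontology terms passed, and among genes that fell 1 pathway and 18 terms passed. Many of the 171 terms had the same counts, 7 risen of 10 members, such as xenobiotic glucuronidation and bilirubin conjugation. Such terms may share their genes, so 171 is not a count of separate themes. Retinol metabolism held 36 risen genes of 68, where 6.03 were expected (adjusted p = 1.71e-17), and metabolism of xenobiotics by cytochrome P450 held 31 of 63 (5.58 expected, adjusted p = 5.3e-14). Both pathways contained the same number of UDP-glycosyltransferases, 45, which made up 29 of the risen genes in each, while 0 of the risen genes were in the P450 list. Starch and sucrose metabolism held 20 of 43 (3.81 expected), lysosome 32 of 145 (12.9 expected) and fatty acid biosynthesis 12 of 29 (2.57 expected). Among genes that fell, dynein complex held 6 of 37 (0.445 expected, adjusted p = 0.00029), transposase activity 4 of 16 (0.193 expected, adjusted p = 0.00165) and cilium movement 4 of 25 (0.301 expected, adjusted p = 0.00812).

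The authors' deposited table gives DESeq2 adjusted p-values and log2 fold changes for 10440 genes. At an adjusted p under 0.01 and at least 2-fold, the authors' deposited table holds 766 higher and 147 lower genes, and all 766 and 147 are among the genes changed at least 2-fold here. The log2 fold changes differed from the authors' deposited table by a median of 0.01 in size. They were further apart for some genes with few counts in 1 strain, such as Aphis_gossypii_newGene_3096, at 1.84 in the authors' deposited table and 5.48 here. Some abundant genes also differed by more than that median, such as the cuticle protein LOC114124292, at 2.36 in the authors' deposited table and 2.63 here.

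The list tests depended on the correlation assumed between genes. With the correlation estimated from the libraries 0 of 29 lists passed after adjustment in limma's camera (7 at an unadjusted p under 0.05), and limma's fry called 20 in 1 direction.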

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

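All alternatives here were fixed before the data were examined. Across them the counts of genes higher and of genes changed at least 2-fold in either direction stayed within 1.5 times the reported ones, with these exceptions. With library totals alone 340 genes were at least 2-fold lower in place of 219; this scaling lowers all fold changes by about 0.15. Leaving out single libraries gave 788 to 2826 lower genes in place of 1611, with 2826 without resistant replicate 1 and 812, 788 and 789 without susceptible replicates 1, 2 and 3 (the cause was not tested). A test against a 2-fold threshold, stricter by construction, called 419 genes, 379 higher and 40 lower. With a correlation estimated per list 0 of 29 lists passed, in place of 19; fry without regard to direction called 28, and other alternatives gave 17 to 20. Taking all genes past the adjusted p, without the fold limit, gave 375 annotation terms in place of 210, as more genes entered.

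Lists far from the threshold changed direction, and the cause was not tested. For muscle structural genes the adjusted p was then 0.892 with library totals alone, 0.817 with DESeq2, 0.897 with the CPM filter and 0.706 with Swiss-Prot members alone, and without single libraries it ranged from 0.539 to 0.921 (0.823 without resistant replicate 2, 0.866 without susceptible replicate 1). For cell cycle genes it was 0.912 with library totals alone, 0.988 with DESeq2 and 0.624 without resistant replicate 3 (range without single libraries 0.0950 to 0.829). For xenobiotic response regulators it was 0.940 with library totals alone, 0.972 with Swiss-Prot members alone and 0.703 without resistant replicate 1 (range 0.421 to 0.953). Transposon-derived genes gave 0.799 with no filter and 0.941 without resistant replicate 3 (range 0.494 to 0.941), heat shock proteins 0.844 without resistant replicate 1 (range 0.161 to 0.844), and odorant and taste proteins 0.972 with Swiss-Prot members alone. Of the other list results 29 lost a call, 19 of them with the estimated correlation, and 8 gained one (7 times the immunity list, 1 time the transposon-derived list with fry, 0.00176), and 6 results of named genes lost theirs; the last were LOC114120105 and LOC114122382 without single libraries.

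Replicate numbers did not pair the libraries: the deviations of same-numbered libraries correlated at -0.01, -0.03 and -0.02. With the replicate block 2109 genes were higher and 1313 lower, and the CYP4 list had an adjusted p of 0.0555. That list also lost its call with no filter (0.0767) and with Swiss-Prot members alone (0.0875), glutathione S-transferases with Swiss-Prot members alone (0.0706) and ribosomal proteins with fry (0.171). The pseudocount alternative was not run, as the table holds counts. In the simulation, run at this depth and number of libraries, 23.5% of genes changed by 0.5 on the log2 scale were recovered. Only 200 of 11149 genes were changed there, while 3994 were called in the data. The same adjusted p limit was therefore stricter in the simulation, so this share does not carry over to the data.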

Other observations

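Of the tests given here, those of scaling, of replicate 1 for the share of higher genes, of gene length, of the make-up of the pools, of all nervous tissue (reworded after its value was seen), of receptor-bearing neurons and of other splits were chosen only after the results were seen, and so were the cilium lists and the genes counted in 1 strain.

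Of 80 genes of the cilium 20 fell and 2 rose in the resistant strain, and the others passed in neither direction. Lists of these genes were written after the dynein terms had been seen, so neither list, nor any test of their members here, is independent evidence. Insects carry cilia on sensory neurons and as sperm tails. Of 53 genes of the moving axoneme 12 fell and 2 rose, with a median log2 fold change of -0.57, and of 28 genes of cilium assembly and transport 9 fell and 0 rose, with a median of -0.50. Adjusted over the list alone, 11 fell and 2 rose in the first and 12 fell and 0 rose in the second. The second list also holds ciliary dynein chains, which are motor parts of the axoneme. Of these, LOC114130122 (-1.72 ± 0.27), a member of both lists, and LOC114122924 (-1.16 ± 0.28) fell, so the lists are not separate in kind. Dynein heavy chain LOC114130757 fell from 24.4 to 11.3 CPM (-1.10 ± 0.17 SE, adjusted p = 0.00173), LOC114128964, a cilia- and flagella-associated protein, from 61.0 to 29.7 CPM (-1.04 ± 0.12) and the Bardet-Biedl syndrome 7 homolog LOC114132703 from 25.7 to 12.7 CPM (-1.01 ± 0.16). The 2 that rose were in the axoneme list, dynein heavy chain LOC114121359, from 1.10 to 6.18 CPM, and the list's most abundant gene, LOC114126506, an outer dense fiber protein, from 65.4 to 117 CPM. The 8 transport genes outside the terms seen before had a median of -0.60, and 126 of 10000 random lists matched on expression reached it.

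This cilium pattern does not come from resistant replicate 1, without which the median was -0.545, against -0.541 with it. A lower share of all nervous tissue stays open: the nervous system median lay 0.48 above that of the cilium genes (0.477 to 3 digits; permutation p = 2e-05, with the cilium lists written after their terms were seen lower and genes not independent), but its members went both ways (quartiles -0.44 and 0.37). A lower share of receptor-bearing neurons stays open too, since the insecticide target receptors lay only 0.13 above (0.132 to 3 digits; permutation p = 0.382). A hypothesis for follow-up is that the lower RFX2-like transcript LOC114129314 and the lower cilium genes share a cause in ciliated sensory cells, which pooled whole bodies cannot show. Measuring both in dissected antennae, with and without RNA interference of LOC114129314, would test it.

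More genes were at least 2-fold higher than lower in the resistant strain, 926 against 219. Under the 2 other scalings tried, the share that was higher moved from 80.9% to no less than 68.0%, so neither of these accounts for it. A larger shift between the strains was not tried, so scaling is not excluded as a cause. Without resistant replicate 1 the share was 77.8%. A closer match of the resistant strain's reads to the reference, and a difference between the strains themselves, stay open, as sequence was not analysed here.

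Resistant replicate 1 stood apart, with 214 genes over 2-fold above and 457 over 2-fold below the other resistant libraries. With the other resistant libraries thinned to its total, 633 genes still differed over 2-fold between replicates 1 and 2 against 214 between replicates 2 and 3, a ratio of 2.96, so lower depth does not account for it. Gene length explained 1.81% of the variance of its deviations. Another make-up of the pooled aphids, such as more moulting individuals, may account for part: the cuticle median lay 0.74 above the other libraries, ribosomal proteins 0.44 above and cell cycle genes 0.29 below. The make-up of the pools and the base composition of the genes were not analysed here, so this stays open.

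In all, 35 genes had at most 3 counts over the libraries of 1 strain and a mean of at least 0.5 CPM, from plain library totals, in the other, 27 with counts in the resistant and 8 in the susceptible strain. Of these, 7 matched the transposon-derived list, against 39 of 10981 genes with a mean of at least 0.5 CPM in either strain (Fisher's exact test, two-sided p = 2.53e-11). That background has no upper limit and was not matched on expression, and related copies are not independent. The p-value therefore does not part a strain difference from a difference in expression level. Among the 35 genes, zinc finger BED gene LOC114131210 had 534 counts in the resistant and 0 in the susceptible strain, and LOC114121959, of the same kind, had 0 and 375. The peroxiredoxin-6-like LOC114126282 had 0 and 1736. Sequence was not analysed, so genes missing from a strain or not matching the reference cannot be told apart from silent ones.

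Splitting the 6 libraries into 3 and 3 in all 10 ways gives too few splits for a share under 0.05. The real split gave 3994 genes past the adjusted p, and the highest of the other splits gave 0 (edgeR; 18 to 156 at an unadjusted p under 0.05, against 5142). For genes changed at least 2-fold the values were 1145 and 0, and for gene lists 19 and 17. In each case 1 of the 10 splits, the real one, gave a count as large. Each other split keeps 2 libraries of a strain together, so it still holds part of the strain difference.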
